A study of Mus musculus with 2 samples.

How the data were processed

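The series held 2 arrays of methylated DNA immunoprecipitation (MeDIP), 1 of untreated MEFs and 1 of MEFs given 100 µM thymidine for 2 days. Per the labels, DNA was sheared to 200 to 1000 bp, Cy5 marked the anti-5-methylcytosine precipitate and Cy3 the input, so a higher ratio means more precipitate signal relative to input. Both arrays had the same dye orientation, so dye bias was not balanced. For the treated array the labels describe the input in 2 ways, as MEFs in its source name and as thymidine-treated in its characteristics, and which culture gave the input is therefore not settled. The labels do not say whether feeder cells were removed before the DNA was purified.

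Per the file headers, the spots were read with Agilent Feature Extraction 11.0.1.1 on a grid of the mm9 build. The deposited intensity values are processed signals, which per the file headers are background-subtracted and scaled between dyes by a linear factor, and raw median intensities of spot and local background. The deposited log10 ratios of Cy5 to Cy3 equalled the log10 ratio of the processed signals within 1e-06 at 97.4% of probes on the untreated and 96.9% on the treated array. The log10 ratio errors are the scanner software's own estimates, per the file headers. A table of the whole series holds log ratios made by the authors, taken as log2 values because of their slope against the scanner log2 ratios. The log base, normalisation and smoothing behind that table are not given in the sources used here. Its column medians were -0.01 and -0.02. Its values correlated at 0.94 on each array with the mean log2 ratio of the raw median intensities within 300 bp. The slopes were 0.93 and 1.07, in a positive direction. Without averaging over neighbours the correlation was 0.92 on each array, and with the mean within 500 bp it was 0.84. No background was subtracted from the intensities in these comparisons. Against the log2 ratio of the processed signals, probe by probe, the authors' values correlated at 0.88 on the untreated and 0.83 on the treated array.

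From these, log2(Cy5/Cy3) of the processed signals was computed and centred on the median of each array, with no loess or quantile step. Of 180465 spots, 5827 were control spots and were left out. Probes were kept if no outlier flag was set in either channel (57 probes were flagged) and the input was well above background on both arrays, which 32018 probes were not. This left 142569 probes (81.6%), 118061 of them with both channels well above background. The difference is thymidine-treated minus untreated. The positions of probes in the text are those of the files, with the first base numbered 1. Differences of single channels were centred on their medians.

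The design planned before the data were examined was by gene, or by coordinate where no gene could be assigned. The files name no genes, and the gene table at hand is of another build, GRCm38.p6, whose coordinates were not used. The plan's fallback was therefore applied to tiled regions. A region was a set of probes whose starts lay less than 1000 bp apart, a gap chosen after the spacing of probes was seen, with at least 3 kept probes. It was counted as higher or lower when its median difference was at least 0.5 in size and at least 80% of its probes shared the sign. Regions had a median of 8 probes over 1644 bp, of which a median of 6 were kept. The named regions are the 12 with the highest and the 12 with the lowest median difference among those with 80% of probes of one sign, and other regions in the text were chosen after their values were seen. The 17 gene lists fixed in advance, among them blood, fibroblast, imprinted and germline genes, were not analysed here for the same reason. With 1 array per group no residual degrees of freedom remain, and no p-value was computed. Slide and scan could not be told apart from the group. Nor could a sort by the blood cell protein CD45, named for the treated sample, or the unsettled origin of its input. The words after thymidine refer to the treated array and name no cause.

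The precision is limited by the number of arrays. Across 15 replicated control probes with 178 spots, the median SD of the log2 ratio was 0.09 on the untreated and 0.11 on the treated array, and 0.14 for the difference. This covers only spots of the same probe within an array. The mean difference between the arrays ranged from -0.42 to 0.63 over these 15 control probes, which is as large as the differences by which regions were counted, and what DNA they measure is not given in the sources used here. The counting of regions was tested on simulated data made by shuffling the probe differences of these arrays over 21518 regions after removal of the level trend and shifting 100 regions by each of 2 sizes. At a shift of 0.5, 51.0% were recovered, at a shift of 1, 100%, and 32 unshifted regions (0.150%) were counted. A shift of 0.5 equals the counting threshold, so the share recovered there is largely set by the rule. The 32 regions hold only for data without the level trend, while the counts reported below keep it. With the trend kept, shuffled differences gave a mean of 213 higher and 5.1 lower regions. Intervals of shares are 95% Wilson intervals. Alternatives were normexp background correction with an offset of 50, loess, quantile and equal-spread scaling, other filters, thresholds and region rules, the precipitate channel alone, removal of the trend with ratio level by lowess with a fraction of 0.2, and the authors' table. Normexp used median signals, where the plan named mean signals, since the files hold no mean signals. Removal of row and column trends on the array surface and other region gaps were added after seeing the data. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.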

Results

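DNA methylation was profiled in mouse embryonic fibroblasts (MEFs), connective tissue cells cultured from C57BL/6 embryos at stage E14.5, with and without thymidine, the deoxynucleoside of thymine. Cells carrying CD45, CD41, CD31 or c-Kit, surface markers of blood progenitors among others, had been depleted before culture. The remaining cells were grown on mitomycin-treated MEF feeders, in plain medium or with 100 µM thymidine for 2 days, and the source label of the treated sample names a CD45 sort. CD45 is a surface protein of blood cells. Methylated DNA was precipitated with an antibody against 5-methylcytosine, labelled with Cy5 and hybridised together with Cy3-labelled input DNA to a tiling array (MeDIP-chip). The log2 ratio of Cy5 to Cy3, centred on the median of each array, gave the precipitate signal of a probe relative to its input. Each condition had 1 array, so no difference between them could be set against a spread between replicates, no test was possible, and every comparison describes these 2 arrays only.

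Each array carried 174638 genomic probes of 45 to 60 bases, placed at a median spacing of 209 bp in 22170 tiled regions of the mm9 genome. In the untreated sample 88.4% of probes were well above background in the input channel and 70.3% in the precipitate channel. The treated sample had 81.7% and 69.2%. The median raw signal was 10.3 times the local background in the input channel of the untreated array and 5.94 times in its precipitate channel, against 10.4 and 4.95 times on the treated array. After filtering, 142569 probes and 21518 tiled regions with at least 3 probes remained. The files gave positions and no gene names, and no annotation of their build was used here, so regions are named by their mm9 coordinates and their gene context is not reported.

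The first question was how the ratio of precipitate to input was distributed in each sample. Both arrays had a long tail of low ratios and a shorter tail of high ones. In untreated MEFs 10220 probes (7.17%, 95% Wilson interval 7.04% to 7.30%) had a centred log2 ratio of at least 1, and 21409 probes (15.0%) had a ratio of -1 or less. In thymidine-treated cells the counts were 10834 (7.60%, interval 7.46% to 7.74%) and 16066 (11.3%). The intervals cover counting of probes only, and probes on overlapping fragments are not independent. The share of probes at or above 1 depended on the processing, and normexp background correction lowered it to 2.87% and 2.88%. The direction between the samples turned round with loess, at 6.92% in untreated and 6.56% in treated cells, and with no filter on dim probes, at 7.88% and 7.81%. The authors' deposited table gave 1.35% and 1.38%. The same probes were largely at the extremes in both samples, with 7348 probes at or above 1 on both arrays where 777 would be shared by independent placement, and 14458 at or below -1 on both where 2413 would be.

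Part of the regions with low ratios lay in long runs. Of the measured regions, 907 (4.22%) had a mean ratio over both arrays of -1 or less, 750 of them with a ratio of -1 or less on each array. Of the 907 regions, 338 lay in 26 runs of at least 5 consecutive regions, which were defined on the mean of both arrays. When the low regions were shuffled within chromosomes 100 times, the mean number of such runs was 0.04 and the highest was 1. The longest run held 90 consecutive regions on chromosome 7 from 20685501 to 24086631, with a median log2 ratio of -2.74 in untreated and -2.49 in treated cells. A run of 31 regions lay on chromosome 2 from 174892772 to 177814338, with medians of -2.29 and -1.93. A further run of 30 regions lay on chromosome 7 from 7289705 to 10762238, with medians of -2.45 and -2.29. Chromosome 4 had a run of 18 regions from 60015121 to 61715954 at -2.71 and -2.33, and chromosome X a run of 15 regions from 24728134 to 32132718 at -2.51 in both samples. The sizes of these ratios are uncertain, since many probes of the runs were not well above background in the precipitate channel. The share that was, on both arrays, was 41.8% in the chromosome 7 run of 90 regions, 55.4% in that on chromosome 2, 45.2% in the chromosome 7 run of 30 regions, 48.6% on chromosome 4 and 51.5% on chromosome X. Over all runs the median ratio was -2.36, and -1.38 over the 1145 of 2234 probes with both channels well above background. That filter favours higher ratios, and at probes outside the runs it moved the median from 0.01 to 0.15. The share of low regions was 12.03% on chromosome 7 and 8.44% on chromosome X, and 0.871% on chromosome 11. The rule for these runs and the chromosomes named were chosen after the values were seen.

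**Figure D1:**
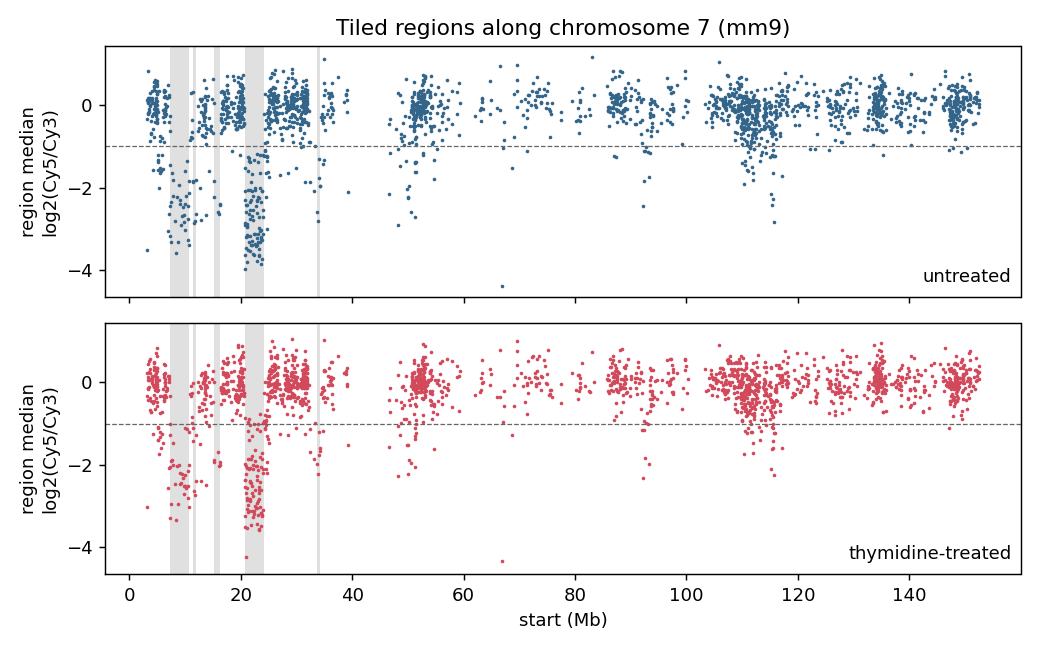
Median centred log2 ratio of precipitate (Cy5) to input (Cy3) of each tiled region along chromosome 7 (x axis, start in Mb, mm9) in untreated (top) and thymidine-treated cells (bottom), 1 array each. Grey bands mark the 5 runs of at least 5 consecutive regions at or below -1 (dashed line) by the mean of both arrays, which held 137 regions.

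At the other end, 33 regions had a median ratio of at least 1 in untreated and 53 in treated cells. Among regions with at least 5 probes, the highest mean level was on chromosome 2 from 157029786 to 157031529, with ratios of 1.42 and 1.28 over 7 probes. A region on chromosome 2 from 172949093 to 172950403 had 1.5 and 1.12 over 5 probes, and a region on chromosome 14 from 56108631 to 56110362 had 1.15 and 1.30 over 9 probes. Probes of a region shared little of their ratio. Adjacent probes under 300 bp apart, within reach of the 200 to 1000 bp fragments, correlated at r = 0.219 across 94190 pairs on each array, and pairs 5 to 50 kb apart at 0.147 and 0.161. In the authors' deposited table the adjacent pairs correlated at 0.739 and 0.742. Its values, however, followed the mean ratio of the raw median signals within 300 bp (r = 0.94), against r = 0.92 for the raw ratio of the single probe. Averaging over neighbours raises such a correlation by construction. These correlations are across probes, which are not independent replicates.

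**Figure D2:**
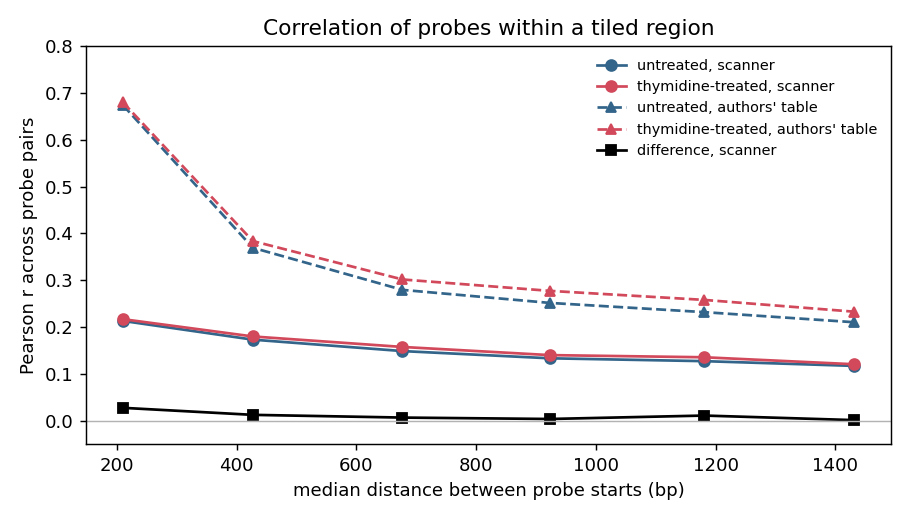
Pearson correlation of the log2 ratio between probes of the same tiled region (y axis) against the median distance of their starts in bp (x axis), for probes 1 to 6 places apart. The scanner ratios (circles, solid lines) go from 0.213 and 0.217 to 0.117 and 0.121, the authors' deposited values (triangles, dashed lines) from 0.674 and 0.680 to 0.210 and 0.233, and the difference between the arrays (squares) stays between 0.002 and 0.028. The deposited values resemble means over neighbouring probes, which raises their correlation by construction.

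The second question was where this ratio differed after thymidine. The arrays were alike at most probes, with a correlation of 0.93 across probes and a median difference, treated minus untreated, of 0.07 (SD over probes 0.36). The scanner software's own error of such a difference had a median of 0.34, and 2.95% of probes differed by more than 2 of these errors, 2611 of them higher and 1596 lower after thymidine. Normally distributed noise with these errors as its SD would give a larger share, so this share shows no excess over scanner error. The split still holds the median difference of 0.07. At a difference of at least 1, which is 2-fold, 1523 probes were higher and 132 lower. The split turned round under some settings. It was 358 higher and 446 lower after quantile normalisation, and 343 and 436 once the trend with ratio level was removed. With normexp background correction it was 21 and 28, and from the precipitate signals alone 88 and 214. Quantile normalisation gives both arrays the same distribution and trend removal centres each level, so both act on the split by construction. The direction stayed with loess (1142 and 234), equal spread (899 and 177) and both channels well above background (241 and 51). It also stayed with no filter (2570 and 346), surface trends removed (1440 and 110) and in the authors' table (15 and 13). Of the 1523 higher probes 1161 were not well above background in the precipitate channel on either array and 226 were measured on both. Of the 132 lower probes 54 were measured on both.

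The difference depended on the level of the ratio. Probes with a mean ratio below -2 had a median difference of 0.49, those between -2 and -1 had 0.31, and those between 0 and 0.5 had -0.01. In the lowest class the median difference of the input signal was -0.48 and that of the precipitate signal -0.01. Many probes at such low ratios were not well above background in the precipitate channel. In the runs of low regions, with a median ratio of -2.36, 1145 of 2234 probes were measured in both channels. The precipitate difference of the lowest class may therefore be a floor value.

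**Figure D3:**
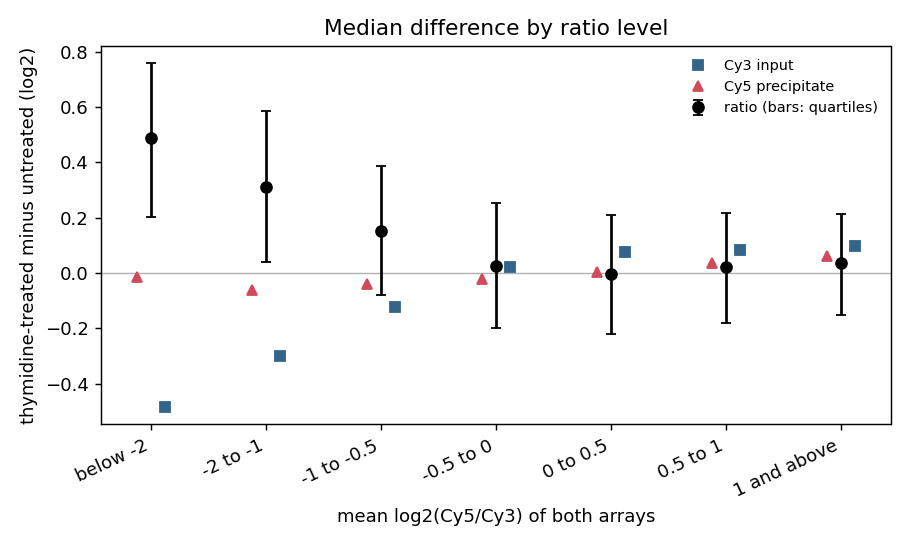
Median difference, thymidine-treated minus untreated, of the centred log2 ratio (black circles, bars from the lower to the upper quartile), of the Cy3 input signal (blue squares) and of the Cy5 precipitate signal (red triangles), in 7 classes of the mean log2 ratio of both arrays (x axis). In the lowest class, with 6024 probes, the ratio differs by 0.49 and the input by -0.48. Many precipitate signals at low ratios are near background, so their differences there are uncertain.

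Over tiled regions, 152 of 21518 had a median difference of at least 0.5 with at least 80% of probes sharing its sign, and 12 had one of -0.5 or less. No region reached a difference of 1 in either direction. The split into higher and lower depended on the scaling. It was 15 and 36 regions after quantile normalisation of the arrays and 16 and 34 once the trend with ratio level was removed. Both of these steps act on the split by construction. In the authors' deposited table it was 4 and 13. Higher regions stayed the majority with loess (109 and 21), equal spread (74 and 15), both channels well above background (78 and 14) and no filter (103 and 4). When probe differences were shuffled among probes of equal level 100 times, a mean of 213 regions (186 to 253) were higher and 5.1 (0 to 9) lower. The SD of the observed region medians was 0.17, as in the shuffled data. The regions with a higher ratio lay at low levels, with a median mean ratio of -0.98, and 75 of the 152 had a mean ratio of -1 or less.

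Among the regions with the highest difference, the region ranked first, on chromosome 3 from 93764947 to 93765484, had no probe well above background in the precipitate channel, so no fold is given. The next, on chromosome 9 from 18207994 to 18209124, was higher by 0.84 (SD over 3 probes 0.31), with ratios of -1.22 in untreated and -0.37 in treated cells. Its difference was 0.53 with the level trend removed, 0.35 with normexp and 0.45 in the authors' deposited table. A region on chromosome 4 from 98049559 to 98051073 was higher by 0.83 (SD over 5 probes 0.48), but by 0.05 over its 2 probes measured in both channels. A region on chromosome 6 from 128836669 to 128837955 was higher by 0.82 (SD over 5 probes 0.49), by 0.44 with normexp and by 0.39 in the authors' deposited table. The region on chromosome 16 from 89015252 to 89015826 was higher by 0.72 (SD over 3 probes 0.34), but its difference was -0.25 without the filter on dim probes. The region on chromosome 12 from 90190936 to 90192214 was higher by 0.68 (SD over 5 probes 0.22), in all 5 probes and all measured in both channels, with ratios of -0.12 and 0.60. Its difference was 0.40 with normexp and 0.33 in the authors' deposited table. The 12 highest regions spanned 0.68 to 0.92. The upper end is the chromosome 3 region without a measured precipitate signal, so its size is uncertain. In all 12 the input signal was lower in the treated sample, with a median difference of -0.43, against 0.19 for the precipitate signal. Choosing regions by a high ratio difference favours a lower input, the denominator. Across probes the difference correlated at -0.79 with the input difference.

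The lowest difference of all measured regions was on chromosome X from 166416350 to 166418062, the most distal measured region of that chromosome, at -0.64 (SD over 9 probes 0.30), with all 9 probes lower. Its ratios were -0.84 in untreated and -1.30 in treated cells. Its difference was -0.998 with quantile normalisation, -0.97 with the level trend removed, -0.88 in the authors' deposited table and -0.09 from the precipitate signals alone. Its input signal was higher by 0.71 in the treated sample, the highest of the 21518 regions, and its precipitate signal differed by -0.09. The neighbouring region from 166316264 to 166317763 differed by 0.07. A region on chromosome 4 from 134065614 to 134067022 had a difference of -0.58 (SD over 4 probes 0.20), and a region on chromosome 17 from 29078715 to 29079260 had -0.56 (SD over 3 probes 0.25), with ratios of 0.59 in untreated and 0.02 in treated cells. The region on chromosome 7 from 87438871 to 87439543 had a difference of -0.55 (SD over 4 probes 0.25), and of 0.02 without the filter on dim probes. The region on chromosome 10 from 16815240 to 16816398 had a difference of -0.55 (SD over 5 probes 0.70), and of 0.06 with normexp background correction. Only 1 of its 5 probes was well above background in the precipitate channel on both arrays, and 2 were on neither, so the size of its difference is uncertain. The 12 lowest regions spanned -0.64 to -0.50. In all 12 the input signal was higher in the treated sample, by a median of 0.32, a sign that the choice of regions likewise favours. The sizes of the named differences depended on the processing. Part of this is by construction, since the regions were chosen by a large ratio difference and the normexp offset shrinks ratios. Of the 24 named values, 19 moved by over 1.5 times or changed sign with normexp, 19 in the authors' deposited table, 9 with quantile normalisation, 9 with the level trend removed, 10 with no filter on dim probes and all 24 from the precipitate signals alone. Over the 12 highest regions the median was 0.40 with normexp, 0.46 with the level trend removed, 0.30 in the authors' deposited table and 0.19 from the precipitate signals alone, and over the 12 lowest it was -0.25, -0.60, -0.30 and -0.23. All 24 had the same sign in the authors' deposited table, which comes from the same arrays and in which only 2 of the 152 higher and 2 of the 12 lower regions passed the size and sign rule.

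**Figure D4:**
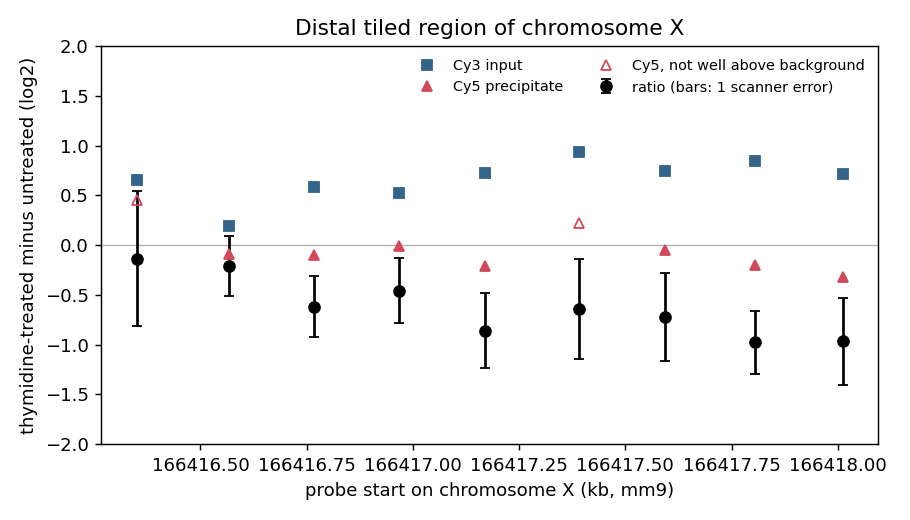
Difference, thymidine-treated minus untreated, at the 9 probes of the distal region of chromosome X (x axis, probe start in kb, mm9), for the centred log2 ratio (black circles, bars of 1 scanner error), the Cy3 input signal (blue squares) and the Cy5 precipitate signal (red triangles, open where not well above background). All 9 ratios lie below 0 and all 9 input differences above 0, from 0.19 to 0.93.

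By chromosome, the differences were close to that of the whole array. The median over probes ranged from 0.05 on chromosome 8 to 0.09 on chromosome 7 among autosomes, and was 0.06 on chromosome X and 0.04 on chromosome Y, where 67 probes were kept. The median input difference was 0.02 on chromosome X and 0.01 on chromosome Y. Of the 152 higher regions 27 lay on chromosome 7, where its share of regions gives 13.9, 20 on chromosome 2 against 12.6, 15 on chromosome 4 against 9.42 and 6 on chromosome X against 6.36. Counts below the share of regions included 4 on chromosome 11 against 11.4, 0 on chromosome 15 against 5.87, 3 on chromosome 6 against 8.31 and 4 on chromosome 1 against 8.43. Chromosomes 7, 2, 4 and X held 236, 78, 79 and 76 of the 907 regions with a mean ratio of -1 or less, in this order.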

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

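The tests and the size rule in this part were chosen after the result was seen. The input channel, which the comparisons use only as a denominator, had a median difference of at least 0.6 in size, with every probe on the same side of 0, in 3 regions of at least 5 probes. On chromosome X from 166416350 to 166418062 the input signal was higher in the treated sample by 0.71. On chromosome 7 from 16131336 to 16132956 it differed by -0.60. That region lies in a depleted run of 5 regions from 15244342 to 16336057, with a median input difference of -0.58 to which it contributes. Probes with a mean ratio below -2 had a median input difference of -0.48, so part of the value goes with its level. The run's input difference was the most negative of the 26 runs, and the chromosome 7 run of 90 regions had -0.23. On chromosome 12 from 90190936 to 90192214 the input differed by -0.63.

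The region of chromosome X also had the lowest ratio difference, -0.64. Its input difference was 0.7096 (SD over 9 probes 0.21) and its precipitate difference -0.0854 (SD over 9 probes 0.24), with 2 probes not well above background in the precipitate channel on either array. With 1 array per group no spread between replicates stands beside these values, only the spreads over probes and over regions. Over the 21518 measured regions the SD was 0.14 for the input difference and 0.09 for the precipitate difference. The ratios of control probes, which combine both channels, differed between the arrays by up to 0.63. Lower methylation at an unchanged amount of DNA and more DNA copies therefore cannot be told apart. Nor can either be told from the sort, an input drawn from another culture, or an input difference from preparation or hybridisation.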

How the results depend on the processing

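The alternatives were planned before the data were examined, except the removal of surface trends and the region gaps of 500 and 2000 bp, which were chosen after seeing the data. The cause of each change was not tested, except that thresholds and filters act by construction. The share of probes at or above the threshold in the untreated and the treated sample, in this order, was 2.87% and 2.88% with normexp, 6.92% and 6.56% with loess, 7.39% and 7.39% with quantile normalisation, 6.5% and 8.34% with equal spread, 7.88% and 7.81% with no filter, 5.73% and 6.27% with both channels well above background, and 1.35% and 1.38% in the authors' deposited table. At thresholds of 0.5 and 1.5 it was 23.3% and 23.5%, and 1.6% and 1.78%. The treated sample had the higher share in the main setting but the lower with loess and with no filter, and the shares are equal by construction with quantile normalisation.

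Probes higher after thymidine numbered 21 with normexp, 358 with quantile normalisation, 899 with equal spread, 2570 with no filter, 241 with both channels well above background, 88 from Cy5 alone, 343 with the level trend removed, 15 in the authors' table, and 15666 and 129 at thresholds of 0.5 and 1.5. Lower probes numbered 28 with normexp, 234 with loess, 446 with quantile normalisation, 346 with no filter, 51 with both channels well above background, 214 from Cy5 alone, 436 with the level trend removed, 13 in the authors' table, and 6318 and 5 at thresholds of 0.5 and 1.5. Other settings stayed nearer the main counts. Higher probes numbered 1142 with loess and 1440 with surface trends removed, and lower probes 177 with equal spread and 110 with surface trends removed.

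Regions higher after thymidine numbered 2 with normexp, 15 with quantile normalisation, 74 with equal spread, 78 with both channels well above background, 0 from Cy5 alone, 16 with the level trend removed, 4 in the authors' table, 0 at a threshold of 1 and 100 with at least 5 probes. Lower regions numbered 3 with normexp, 21 with loess, 36 with quantile normalisation, 4 with no filter, 6 from Cy5 alone, 34 with the level trend removed, 0 at a threshold of 1, 6 with at least 5 probes and 19 with no sign rule. Other settings stayed nearer the main counts. Higher regions numbered 109 with loess, 103 with no filter, 122 with the mean over probes, 207 with no sign rule and 124 with surface trends removed. Lower regions numbered 15 with equal spread, 14 with both channels well above background, 8 with the mean over probes and 12 with surface trends removed. Region gaps of 500 and 2000 bp gave 154 and 149 higher and 12 and 11 lower. Of the 152 higher regions, 1 was kept with normexp, 40 with both channels well above background and 98 with surface trends removed. Of the 12 lower regions these settings kept 1, 6 and 6. Quantile normalisation kept 15 of the 152 and 12 of the 12, and removal of the level trend kept 16 and 12. With no filter 58 and 3 were kept, with equal spread 60 and 11, and with loess 87 and 9. The authors' table kept 2 of the 152 and 2 of the 12, so its 13 lower regions were mostly others, and Cy5 alone kept 0 and 0.

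Of 263 values of the 24 named regions under alternatives, 206 moved by less than the SD over their probes, 54 moved by more and 3 changed sign. Those were the regions on chromosome 16 at 89015252 (-0.25 with no filter), chromosome 10 at 16815240 (0.057 with normexp) and chromosome 7 at 87438871 (0.016 with no filter). No paired analysis was possible because each group had 1 array. Shifts of gene lists, centring on housekeeping genes and the choice of promoter probes were not run, since no gene could be assigned. Signal over background, 5.94 and 4.95 in the precipitate channel, limits what can be read from depleted regions.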

Other observations

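The test of array-to-array noise, the comparison of adjacent with distant probes, the use of the level trend as an explanation and the shuffles were chosen after the results were seen, as were the removal of surface trends and the checks of the depleted runs. The removal of the level trend from the differences had been decided before the data were examined. The depleted runs held 2234 kept probes with a median log2 ratio of -2.36, against 0.01 at the other 140335 probes. Subtracting the median of all probes of the same length left -2.04. The 1145 probes of the runs with both channels well above background had -1.38, against 0.15 at the other probes under the same filter. The median difference after thymidine was 0.29 in the runs and 0.06 elsewhere, but -0.07 and 0.00 once the level trend was removed. All 26 runs had a median difference above 0 before that step, and 21 had one below 0 after it. Without a gene annotation of the build, what these blocks contain is not reported here.

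Neighbouring probes shared little of their log ratio. Noise of dim spots should vanish among bright spots, and adjacent probes in the brightest class of spots correlated at 0.1722. This argues against it only weakly. Ratio and signal correlated at 0.448 across probes, so choosing bright spots can narrow the range of ratios and lower a correlation. Adjacent probes of any brightness outside the depleted runs correlated at 0.1459. Noise that differs from array to array is argued against by the correlation of 0.9326 between the arrays. Adjacent probes correlated by 0.0677 more than probes 5 to 50 kb apart, and by 0.0803 more outside the depleted runs, which is consistent with ratios set mainly by the single probe and not by the precipitated fragments. No biological explanation was tested.

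Far more regions were higher than lower after thymidine, 152 against 12. A gradient over the array surface is argued against as the whole cause, since 91.1765% of the regions counted with surface trends removed were higher. For spots near background the settings disagreed. With both channels well above background 84.7826% of the counted regions were higher, which argues against them as the whole cause. With normexp background correction few regions were counted, 2 higher and 3 lower (40.0% higher). Its offset shrinks ratios by construction, so these few regions cannot decide. Whether spots near background gave part of the excess stays undecided. The counts fell to 78 higher regions with both channels well above background and 124 with surface trends removed. Of these, 40 and 98 were among the 152, so these factors bear on which regions were counted. With the level trend removed 32.0% of counted regions were higher, but that step centres the difference at each level and so largely fixes this outcome, and it does not decide whether the trend caused the excess. Shuffling differences among probes of equal level, which keeps the trend, gave a mean of 212.58 higher regions (186 to 253) and 5.1 lower (0 to 9). The observed 152 and 12 both lay outside the shuffled range. The trend with independent probe noise thus gave a larger excess of higher regions than was observed. It gave fewer lower and more higher regions than observed in every shuffle, which argues against it as a full account of the counts. Whether it gave part of the excess was not decided. Whether thymidine, the sort, the origin of the input or the hybridisation set the trend stays open with 1 array per group.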
